A study of Mus musculus with 7 samples.

How the data were processed

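Genomic DNA of 7 cell samples labelled with Cy3 was hybridised together with normal spleen DNA labelled with Cy5 to Agilent oligonucleotide arrays, per the labels' protocols. The sex and strain of the spleen donor are not given in the sources used here. Agilent Feature Extraction made the scanner files, per the submitters' processing notes and the file headers, which name version 9.5.3.1 for 6 arrays and do not name it for T1. The processed signals are intensity values, background-subtracted and dye-normalised with linear factors, per the file headers, which the T1 file lacks. The log ratios in the scanner files are log10 of red over green, per the file headers. The deposited series matrix holds log2 ratios of cells over spleen: its values were -3.322 times the log10 of red over green within 0.01, except at 44 to 289 spots per array, and its column medians were 0.0087, 0.0601, -0.0024, 0.0009, 0.0503, -0.0014 and 0.0069 in the order TmMSCs, T1, RT2, B6-mMSCs-p12, B6-mMSCs-p28, Bc-mMSCs-p12 and Bc-mMSCs-p28. How the authors scaled or centred the matrix beyond this is not given in the sources used here.

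The log2 ratio of the processed Cy3 over the processed Cy5 signal was taken per spot, without loess or quantile normalisation, averaged over spots of a probe and centred on the median of the autosomal probes of each array. The direction rests on the dyes in the labels and on the channel that fell to background in the deepest losses, the cells' Cy3. A planned check with lymphocyte receptor loci could not be made, because the only array name that met the fixed prefixes was Ighmbp2, which is not a receptor gene. Control spots (5082 to 5099 per array) were left out. So were non-uniform and population outlier spots, and spots not well above background in the spleen channel (246 to 2842 further spots per array). The 235402 distinct probes of median length 60 included 220668 on the 19 autosomes, 11951 on X and 593 on Y. Positions are mm8, the build that the labels and the headers of 4 files name, and T1 carries the same positions. The files of the B6 pair hold positions of another build, so their probes were placed by probe name through the other 5 files. Names come from the files of the B6 pair, with 106820 probes named through RefSeq accessions of the table given (assembly GRCm38.p6, used for names only), and 67.4% of probes carry a gene or transcript name.

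Each chromosome was segmented with PELT (squared error, at least 5 probes per segment, penalty of 10 times ln(n) times the noise variance). The noise SD came from differences of neighbouring probes. Segments were called gained or lost at a mean of 0.25 or more in size, and deep or high at 1 or more. Adjacent deep segments were merged for description. A whole chromosome was called where its median passed 0.25 and over 80% of its probes lay in segments called that way. Differences between arrays were segmented in the same way, the spleen channel being common to both. Overlaps and breakpoints (within 5 probes, same sign of step) were set against 1000 rotations along the genome for 21 pairs of arrays, as a description. A gene's value is the mean over the probes that carry its name, or, under 3 probes, the mean of its segment, and its error is the SD over probes. Of 117 listed genes, 104 had probes and 13 did not, Cdkn2b, Braf and Atr among them. Random gene lists (10000) were matched on size only.

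The samples, comparisons, thresholds, gene lists, naming rule and most alternative settings were fixed before the data were examined. Genes are named by this rule: a fixed set that includes Cdkn2a, Cdkn2b, Mtap, Trp53, Rb1, Mdm2, Myc, Cdk4 and Runx2 in every array, then list members in deep or high segments of any array, then list members in called segments by size, up to 25 per array, and then the 5 largest called segments under 5 Mb per array and per difference, with up to 3 gene names each. Other genes of differences are list members in called segments, and regions outside the rule (Mfap1a, Luzp1, Rbfox1 and Dmd) were chosen after their values were seen. Transcripts named only by a GenBank accession are not printed. The comparison of B6-mMSCs-p28 with TmMSCs was added after the data were seen.

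Alternatives were normexp background correction (offset 50), the series matrix values, centring on the density peak or on the median of the autosome medians, leaving out only control spots, intensity loess, lowess on the GC content of the probes, other penalties, other call thresholds and minimum segment sizes. Normexp was planned on mean signals, but only the files of the B6 pair hold these, so it was run on median signals. The span of the GC lowess was raised after a smaller one failed at tied GC values. The segmentation was tested on simulated data: noise with no shift gave 0 called probes in all arrays except T1, with 20. In B6-mMSCs-p28, simulated losses of 3 log2 units over 20 probes were recovered in 7 of 15 cases, against 15 of 15 in every other array. Scan days, per the file headers, were the same for TmMSCs and RT2, for the B6 pair and for the Bc pair, and not given for T1. Scan day is thus no difference within these 3 pairs, but between the pairs it cannot be told apart from the cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The chromosome painting, expression and tissue array data that the series describes were not analysed here.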

Results

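Array comparative genomic hybridisation was used to measure DNA copy number in 7 samples of murine mesenchymal stem cells (MSCs) and tumours, each against normal spleen DNA. TmMSCs are a tumourigenic MSC line, and T1 and RT2 are tumours that were derived from it. B6-mMSCs and Bc-mMSCs are newer marrow cultures of the strains C57BL/6 and BALB/c, each with an array labelled p12 and an array labelled p28. Whether p12 and p28 of a strain come from the same culture is not given in the sources used here. Each group held 1 array with 238202 spots that were not controls, so no test between groups was possible, no p-value is given, and every SD is over probes of 1 array. The median probe spacing was 7845 bp on the mm8 build. The number of arrays limits the precision, and the noise between neighbouring probes (SD, log2) was 0.425 in TmMSCs, 0.206 in T1, 0.317 in RT2, 0.228 in B6-mMSCs-p12, 0.875 in B6-mMSCs-p28, 0.20 in Bc-mMSCs-p12 and 0.16 in Bc-mMSCs-p28. B6-mMSCs-p28 also had the lowest median background-subtracted Cy3 signal, 79.8 against 206.8 to 512.6 on the others. All values below are log2 ratios of cells over spleen.

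The question of the series was which genetic changes mark MSC cultures that form tumours. Segments were called gained on 4.2% and lost on 11.9% of autosomal probes in TmMSCs, 9.8% and 20% in T1, and 32.2% and 34.4% in RT2. B6-mMSCs-p12 had no called segment, and B6-mMSCs-p28 had 4.1% gained and 11.9% lost. Bc-mMSCs-p12 had 12.6% gained and 18.3% lost, and Bc-mMSCs-p28 37.5% and 18.7%. Whole-chromosome loss of chromosome 7 was called in 6 of the 7 arrays, all but B6-mMSCs-p12, and in 5 under normexp background correction, where Bc-mMSCs-p12 had 0 whole chromosomes lost. The balance of gains and losses depended on the centring, the scaling and the call threshold. Of the called probes, 32.9% were gained in T1, 25.6% in B6-mMSCs-p28, 40.9% in Bc-mMSCs-p12 and 66.8% in Bc-mMSCs-p28. Centring on the density peak gave 20.5% in T1 and 66.6% in B6-mMSCs-p28, and centring on the median of the autosome medians gave 20.5% in T1 and 18.5% in Bc-mMSCs-p12. Normexp background correction gave 55.7% in T1, and intensity loess gave 56.5% in Bc-mMSCs-p28. A call threshold of 0.35 gave 63.8% in Bc-mMSCs-p12 and 33.8% in Bc-mMSCs-p28, and a threshold of 0.15 gave 59.7% in B6-mMSCs-p28.

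**Figure D1:**
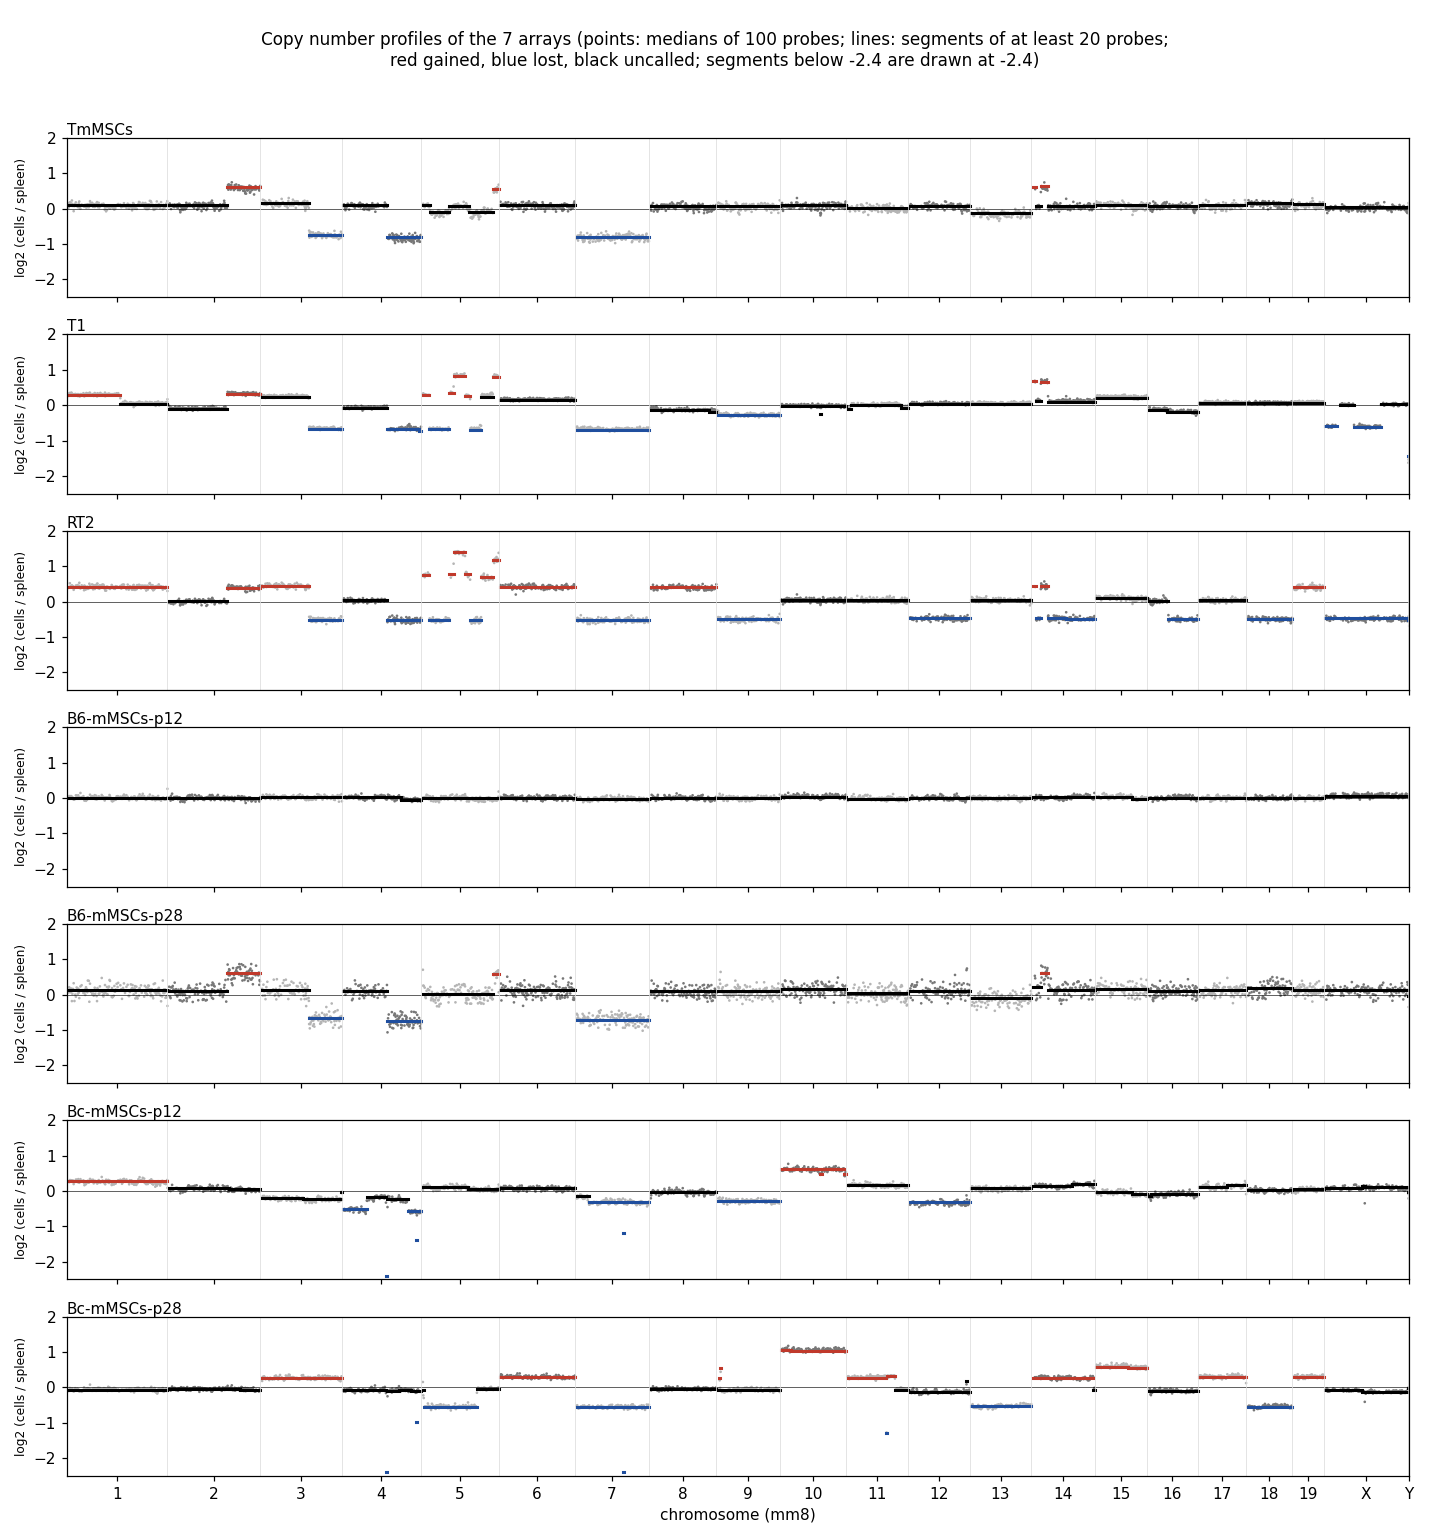
Log2 ratio of cells over spleen along the genome (mm8) for the 7 arrays; points are medians of 100 probes and lines are segments of at least 20 probes, red where gained, blue where lost and black where uncalled. TmMSCs and B6-mMSCs-p28 share losses on chromosomes 3, 4 and 7 and gains on chromosomes 2, 5 and 14, and B6-mMSCs-p12 shows no called segment.

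Cdkn2a, a gene of the Rb and p53 tumour suppressor pathways, was deeply lost in every array except B6-mMSCs-p12. Its 4 probes on chromosome 4 (88748620 to 88763451) averaged -4.67 ± 0.83 in TmMSCs, -4.51 ± 0.70 in T1, -4.61 ± 0.71 in RT2 and -3.69 ± 0.89 in B6-mMSCs-p28. They averaged -5.48 ± 0.62 in Bc-mMSCs-p12 and -4.55 ± 0.69 in Bc-mMSCs-p28, against -0.12 ± 0.22 in B6-mMSCs-p12. In TmMSCs, T1, RT2 and B6-mMSCs-p28 the deep loss spanned the same 20 probes (88738012 to 89021043, 283.0 kb) and left Mtap, a methionine salvage enzyme gene, at -0.11, -0.07, -0.18 and -0.09. In both Bc arrays it spanned 2740.3 kb (86448108 to 89188386) and took in Slc24a2, Mllt3, the interferon gene Ifnb1, Mtap and Dmrta1. Mtap then stood at -4.53 ± 0.87 in p12 and -3.99 ± 0.97 in p28. Over the 20 probes the median background-subtracted signal of the cells (Cy3) was 13.7 in TmMSCs against 397.0 for spleen (Cy5), and 7.6 against 381.3 in B6-mMSCs-p28. Cells were not well above background at 1, 6, 2 and 3 of the 20 probes in TmMSCs, T1, RT2 and Bc-mMSCs-p12, so the size of the ratio over the 20 probes is only a bound in these arrays, and at 0 probes in B6-mMSCs-p28 and Bc-mMSCs-p28. Normexp background correction shrank the Cdkn2a ratio in all 6 arrays with the loss, to values from -2.08 in RT2 to -1.18 in B6-mMSCs-p28, and the deep-loss call ended in TmMSCs and B6-mMSCs-p28. Its offset of 50 exceeds the median Cy3 signal over the 20 probes, 7.6 to 23.0 in these 6 arrays. The offset thus limits how low the ratio can fall, and the shrinkage does not speak against the loss. In B6-mMSCs-p28 the deep-loss call also ended with a segmentation penalty of 20 in place of 10.

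**Figure D2:**
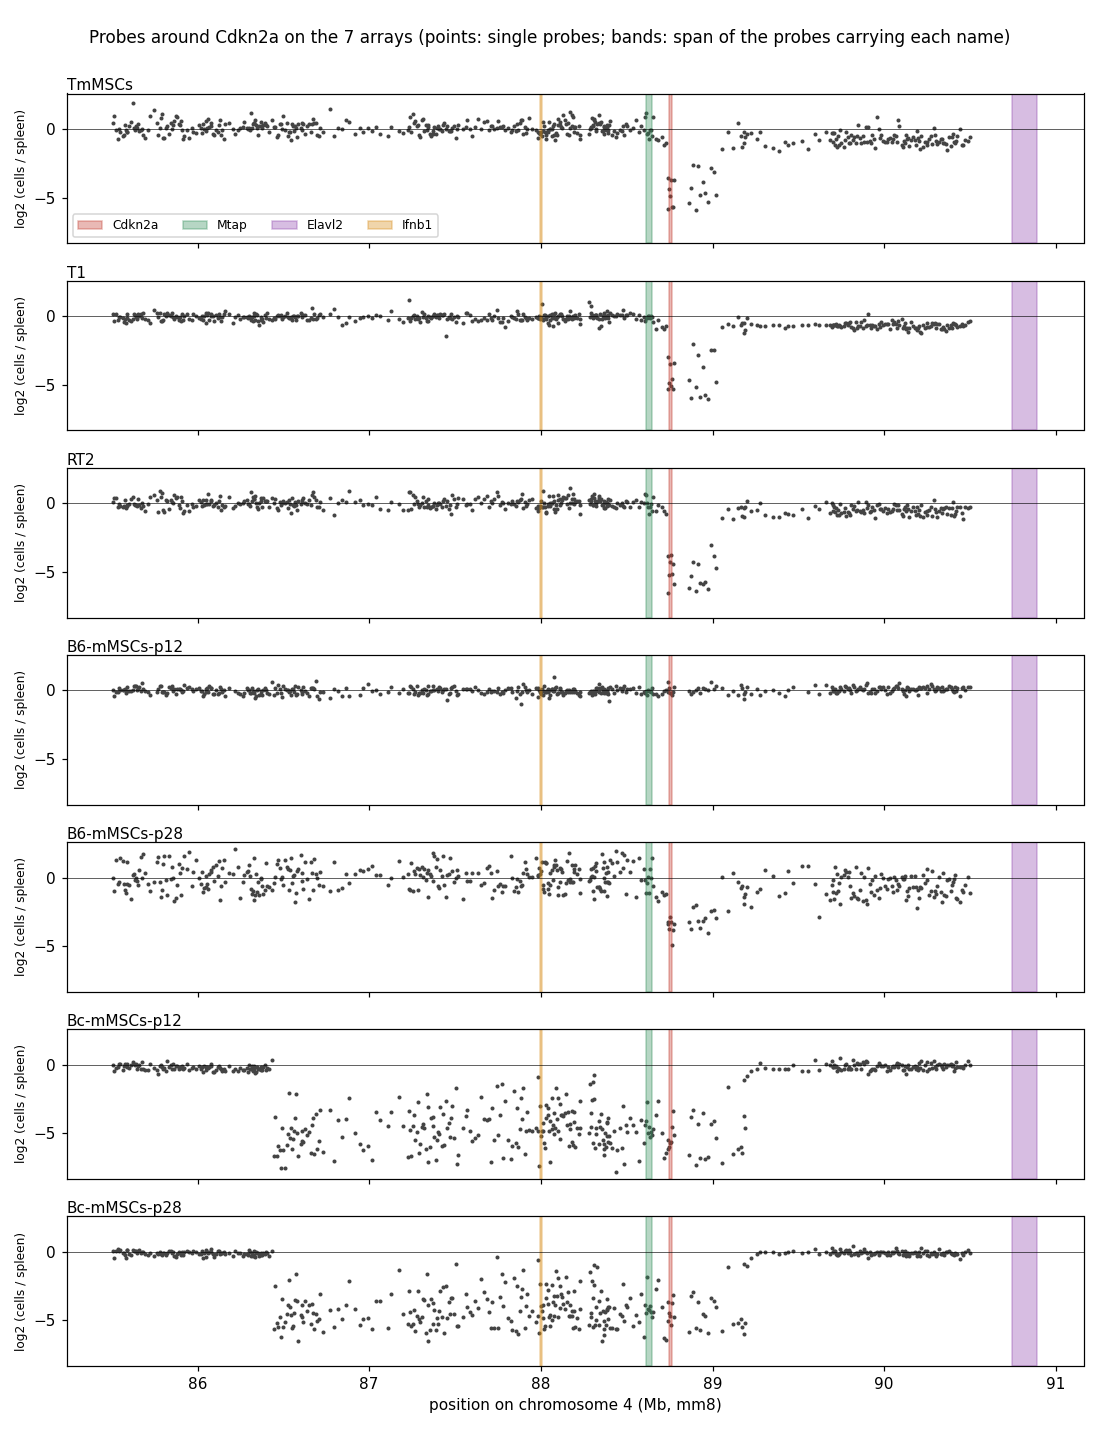
Log2 ratio of cells over spleen of single probes around Cdkn2a on chromosome 4 (position in Mb, mm8) in the 7 arrays; coloured bands mark the span of the probes named Cdkn2a, Mtap, Elavl2 and Ifnb1. The deep loss covers 283.0 kb in TmMSCs, T1, RT2 and B6-mMSCs-p28 and 2740.3 kb in both Bc arrays.

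TmMSCs were compared with the tumours that were derived from them. The TmMSCs profile held a gain of distal chromosome 2 (0.61), losses of distal chromosome 3 (-0.73), of chromosome 4 from 89053298 to its end (-0.81) and of all of chromosome 7 (-0.79), and a gain of distal chromosome 5 (0.56). Brca2, a gene of homologous recombination, lay in the chromosome 5 gain at 0.48 ± 0.57. Trp73, a p53 family member, was lost at -0.70 ± 0.54 and Alpl, the bone alkaline phosphatase gene, at -0.67 ± 0.53. Of the 35556 called probes of TmMSCs, 35549 were called the same way in T1 and 35554 in RT2, and the highest of 1000 rotations of the calls along the genome gave 25055 and 28482. Within 5 probes, 9 of the 10 TmMSCs breakpoints recurred in T1 and 9 in RT2, against at most 1 in the rotations.

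Both tumours carried a rearranged chromosome 5 that was uncalled in TmMSCs outside its distal end. Kit and Pdgfra, receptor tyrosine kinase genes, stood at 0.07 ± 0.40 and -0.11 ± 0.36 in TmMSCs, 0.78 ± 0.30 and 0.78 ± 0.20 in T1, and 1.30 ± 0.32 and 1.33 ± 0.26 in RT2. The RT2 segment that held them (63819931 to 86568200, 1827 probes) averaged 1.39 ± 0.33. Chek2, a checkpoint kinase gene, was lost in both tumours (-0.73 ± 0.23 and -0.54 ± 0.56), as were Spp1 and Ibsp, genes of bone matrix proteins, by the segment that held them (-0.53 in RT2). Brca2 rose further, to 0.72 ± 0.19 in T1 and 1.07 ± 0.44 in RT2. The tumours shared 18 breakpoints, and of 30251 T1 probes whose call was absent from TmMSCs, 30237 were called the same way in RT2, against at most 21761 when these T1 calls were rotated 1000 times. Of 111324 RT2 probes whose call was absent from TmMSCs, the same 30237 (27.2%) were called alike in T1, which is below the highest of their rotations (35534). The 30251 T1 probes included 8257 of a chromosome 1 segment (0.28) and 11929 of chromosome 9 (-0.29), near the call threshold of 0.25. Both segments were uncalled in T1 at a threshold of 0.35, so the count of 30237 depends on the threshold. The whole-chromosome loss of chromosome 9 in T1 also ended under loess and under normexp.

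**Figure D3:**
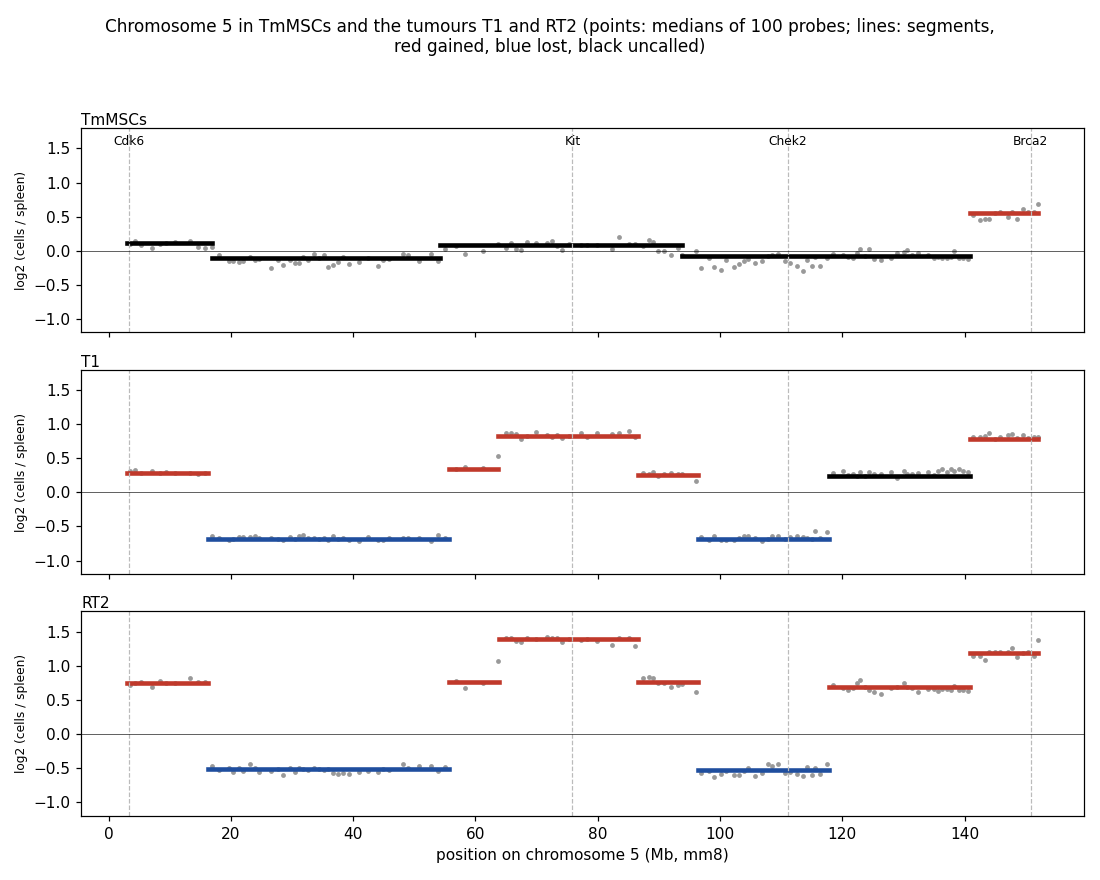
Log2 ratio of cells over spleen along chromosome 5 (position in Mb, mm8) in TmMSCs, T1 and RT2; points are medians of 100 probes and lines are segments, red where gained, blue where lost and black where uncalled. The segment that holds Kit is uncalled in TmMSCs, at 0.83 in T1 and at 1.39 in RT2.

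In the difference of T1 minus TmMSCs, 2.7% of probes lay in segments called higher and 10.9% in segments called lower. Pdgfra (0.89) and Kit (0.70) were higher. Chek2 (-0.62) was lower, as were, by their segments, Ctnnb1, the beta-catenin gene (-0.37), and Atm, a DNA damage kinase gene (-0.37). In RT2 minus TmMSCs 37.8% were higher and 22.5% lower. Pdgfra (1.44), Kit (1.22) and Cdk6, a G1 kinase gene (0.69), were higher, and Apc (-0.70), Smad4 (-0.57) and Rb1 (-0.55), tumour suppressor genes, were lower. In RT2 minus T1 21.5% were higher and 14.4% lower, with Rbl2 (0.77) and Wwox (0.55) higher and Rb1 (-0.47) and Fhit (-0.57) lower. RT2 alone of these 3 gained chromosomes 1, 6, 8 and 19 and lost chromosomes 12 and 18 as a whole, of which the gain of chromosome 8 ended with centring on the density peak. Chromosome 14 of RT2 also met the rule for a whole-chromosome loss, with 82.6% of its probes lost, but 17.4% were gained. Centring moved these counts: the higher share of called probes was 20%, 62.7% and 59.9% in the 3 differences and 3.8%, 12.1% and 37.4% with centring on the density peak. For T1 minus TmMSCs it was 52.1% under loess and 42.0% under normexp. The whole-chromosome loss of chromosome 9 in T1 had a median of -0.27, close to the threshold of 0.25, and 1 of its 2 whole-chromosome losses ended under loess and under normexp.

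The Y chromosome, with the male-linked genes Usp9y, Uty and Zfy1, had a median of -1.52 in T1 and -0.52 in RT2, against 0.00 in TmMSCs. RT2 was lost over all of X (segment mean -0.47), whereas T1 was lost in 2 blocks of X (-0.6 and -0.62) and uncalled between and after them (0.0 and 0.02). T1 calls of only 5 probes held Adamts18 on chromosome 8 (1.72 ± 2.54) and Nphp4 on chromosome 4 (-2.34 ± 1.08). A 32-probe T1 gain on chromosome 14 (68212568 to 68418241) held Loxl2, a lysyl oxidase family gene, Entpd4 and Slc25a37, a mitochondrial iron carrier gene, at 1.14 ± 0.17. The corresponding RT2 gain stood at 0.45 ± 0.44. Its flanks were lost in RT2 (-0.47 and -0.48) and uncalled in T1 (0.10 on each side). The step up was thus 0.91 in RT2 and 1.03 in T1.

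B6-mMSCs-p28 was compared with B6-mMSCs-p12. B6-mMSCs-p12 had no autosomal segment beyond -0.05 or 0.04, and Cdkn2a (-0.12), Rb1 (0.02), Mdm2 (-0.04) and Runx2 (0.07) were uncalled. Lower in B6-mMSCs-p28 than in p12 were Cdkn2a (-3.57), Trp73 (-0.87), Alpl (-0.88), and by their segments the growth control genes Jun (-0.73), Mycl1 (-0.73), Ccnd1 (-0.69) and Hras1 (-0.69). Genes called higher were Rbl1 (0.86), Aurka, a mitotic kinase gene (0.77), Wnt5a (0.77), Brca2 (0.75) and, by their segments, Bub1, a spindle checkpoint kinase gene (0.62), and E2f1 (0.62). Segments called higher covered 4.1% of probes and segments called lower 11.9%. The higher share of called probes was 25.6%, and 56.0% with centring on the density peak.

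The called segments of B6-mMSCs-p28 were those of TmMSCs. Of its 35043 called probes, 34954 (99.7%) were called the same way in TmMSCs, against at most 24038 in 1000 rotations. Distal chromosome 2 stood at 0.60 against 0.61, distal chromosome 3 at -0.67 against -0.73 and chromosome 7 at -0.71 against -0.79. Within 5 probes, 4 of its 7 breakpoints matched a TmMSCs breakpoint, against at most 1 in the rotations. Medians of 100-probe bins correlated at 0.86 across 2216 bins, which are not independent replicates, whereas single probes correlated at -0.16. The difference of these 2 arrays, a comparison added after the profiles were seen, held 0 called probes at a noise SD of 1.149. On loess-normalised values it held 33430 (15.1%), where the levels of B6-mMSCs-p28 were smaller but ran in the same direction in 7 of 7 large TmMSCs segments. Private changes of B6-mMSCs-p28 were poorly detectable: simulated losses of 1 log2 unit over 80 probes were recovered in 0 of 15 cases, and over 400 probes in 14 of 14. Smaller shifts over 400 probes were mostly missed: losses of 0.5 were recovered in 1 of 15 cases and gains of 0.5 in 0 of 14. The simulation used the noise of the single array, and the difference from TmMSCs was noisier.

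**Figure D4:**
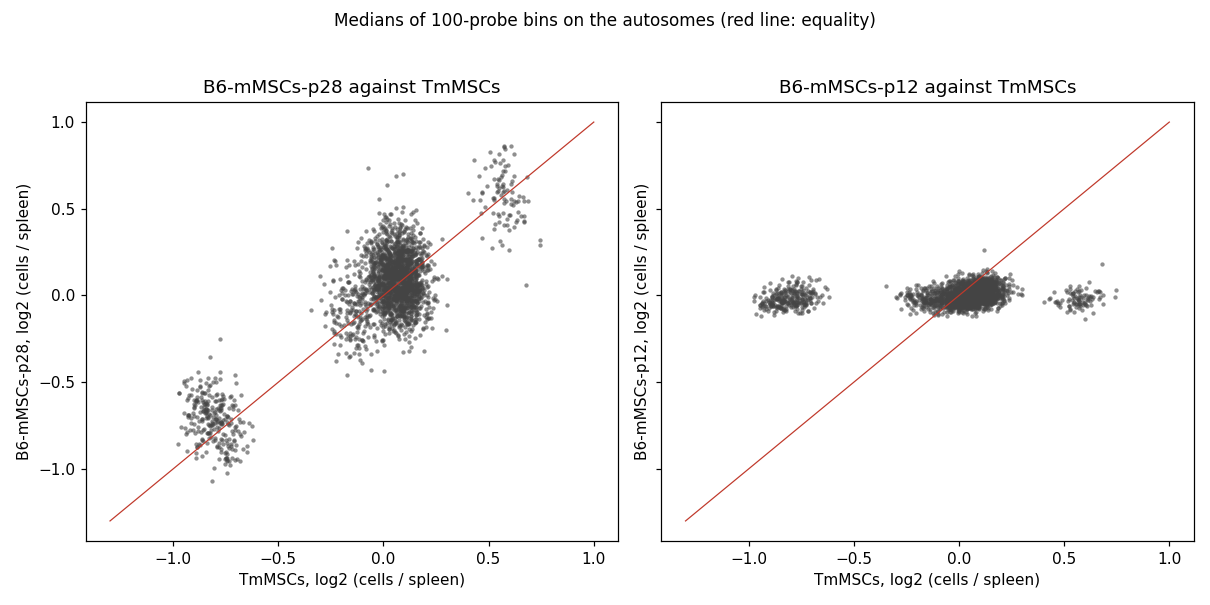
Medians of 100-probe bins (log2 ratio of cells over spleen) on the autosomes, with TmMSCs on the x axis and B6-mMSCs-p28 (left) or B6-mMSCs-p12 (right) on the y axis; the red line marks equality. The bins of B6-mMSCs-p28 form 3 groups along the line (r = 0.86), and those of B6-mMSCs-p12 stay near 0.

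Bc-mMSCs-p28 was compared with Bc-mMSCs-p12. In both, Cdkn2a and Mtap were lost and chromosome 10 was gained, where Mdm2, the ubiquitin ligase gene that restrains p53, stood at 0.70 ± 0.18 in p12 and 1.08 ± 0.03 in p28. Cdk4, a G1 kinase gene of the same chromosome, stood at 0.47 and 1.03 by its segment. Nf1, the neurofibromin tumour suppressor gene, stood at 0.11 ± 0.23 in p12 and was lost in p28 (-1.33 ± 0.27), in an 829.0 kb segment of chromosome 11 (78960597 to 79789550) with Rab11fip4 and Utp6. Myc, the transcription factor oncogene, stood at -0.02 in p12 and 0.59 in p28 by its segment. Birc3 (0.90 higher) and Birc2 (0.80 by its segment), genes of apoptosis inhibitors, and Yap1 (0.84), a Hippo pathway coactivator gene, were higher in p28.

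Kit (-0.66) and Pdgfra (-0.58) were lower in Bc-mMSCs-p28 than in p12, opposite in sign to the tumours T1 and RT2 against TmMSCs. Apc (-0.62), Ptch1 (-0.57), Smad4 (-0.53) and Tert, the telomerase gene (-0.42), were also lower, and the bone transcription factor gene Sp7 was higher (0.54). Segments called higher covered 18.9% of probes and segments called lower 22.3%. Bc-mMSCs-p12 alone of the pair carried whole-chromosome calls on chromosomes 1 (gained), 9 and 12 (lost), and p28 alone gained chromosomes 3, 6, 14, 15, 17 and 19 and lost chromosomes 13 and 18. Some of these calls lay near the threshold: in p12 those of chromosomes 9 and 12 ended under normexp, and that of chromosome 1 ended under normexp, GC lowess and both other centrings. In p28 the gains of chromosomes 3, 14 and 17 ended under loess. The pair shared 23558 called probes, 34.6% of those of p12 and 19% of those of p28, below the highest of 1000 rotations (39312). Breakpoints were shared more closely, 18 of 28 in p12 against at most 2 in the rotations, and 14 of 16 without the steps inside the shared chromosome 4 deletion. Of these 14, 8 were edges of shared focal regions for which an inherited strain difference stays open. A focal drop on chromosome 10 also had edges in both arrays, with steps of -1.27 and 1.26 in p12 and -1.16 and 1.14 in p28. It was uncalled in p28 (-0.11) and so was not among those regions, and a strain difference was not tested there. The higher share of called probes was 45.9%, 63.6% with centring on the density peak and 72.3% with centring on the median of the autosome medians.

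Shared focal losses of the Bc arrays were seen at Mfap1a on chromosome 2 (-3.12 in p12, -2.65 in p28), Luzp1 on chromosome 4 (-4.05, -3.71), Rbfox1, a splicing factor gene on chromosome 16 (-1.2, -0.70), and Dmd, the dystrophin gene on X (-0.72, -0.63). A region of chromosome 7 with no named gene (94974876 to 95749967) stood at -1.19 in p12 and -4.19 in p28.

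The gene lists fixed in advance were counted by called segment. In the list of genes gained in human osteosarcoma, 9 of 10 measured members were gained and 1 lost in Bc-mMSCs-p28, with Myc (0.59), Mdm2 (1.08), Cdk4 (1.03) and Runx2, an osteoblast transcription factor gene (0.32), among the gained. The median of the list was at percentile 99.7 of 10000 random lists of that size, and no member was called in TmMSCs, T1, RT2 or B6-mMSCs-p28. In B6-mMSCs-p28, however, 4 were gained with centring on the density peak and at a threshold of 0.15, and in T1 2 were gained under normexp and at 0.15. In Bc-mMSCs-p12 2 of the 10 were gained and 0 lost (percentile 95.9). Most gained members of Bc-mMSCs-p28 lay near the threshold: 6 stayed gained under loess and 4 at a threshold of 0.35, against 9 under normexp, GC lowess and both other centrings. Of the 24 oncogenes, 7 were lost and 0 gained in TmMSCs (percentile 33.3) and in B6-mMSCs-p28 (6.6), and 10 lost and 2 gained in T1 (35.0). In RT2 14 were lost and 6 gained (3.3), in Bc-mMSCs-p12 10 lost and 1 gained (0.1), and in Bc-mMSCs-p28 7 lost and 10 gained (9.7). The losses of Bc-mMSCs-p12 were 0 at a threshold of 0.35, 7 under normexp, 13 with centring on the median of the autosome medians and 14 at 0.15. The gains of Bc-mMSCs-p28 were 5 at 0.35 and 8 under loess, and the losses of T1 were 7 under normexp, under loess and at 0.35. In B6-mMSCs-p28 4 were gained with centring on the density peak, and 3 under loess and at 0.15. Of all named genes, 14.8% were lost in TmMSCs, 24.9% in T1 and 36.2% in RT2, and 30.0% were gained in RT2 and 35.9% in Bc-mMSCs-p28. Of 13 mitosis and telomere genes, 8 were gained and 2 lost in RT2 (percentile 95.3), and 5 were gained with centring on the density peak. Other tumour suppressor genes were gained at 9 and lost at 4 of 18 in Bc-mMSCs-p28 (percentile 90.5), the lost ones including Nf1, but 5 were gained under loess and 2 at a threshold of 0.35, with 4 lost in both. In the p53 network 5 of 11 were lost in T1 (percentile 11.8) and 5 in RT2 (30.1), with 3 in T1 under normexp, under loess and at 0.35. In the G1/S and Rb network 4 of 15 were lost in TmMSCs (72.3), Cdkn2a among them. Of the osteogenic, adipogenic and Wnt genes, 8 of 14 were gained in Bc-mMSCs-p28 (percentile 95.1), 5 under loess and 2 at a threshold of 0.35, and 5 of 14 were lost in RT2 (70.2), near the share of all named genes. In the Cdkn2 neighbourhood 4 of 5 measured members were lost in both Bc arrays and 3 of 5 in the other arrays with a Cdkn2a loss; Bc-mMSCs-p12 had 3 under normexp and 5 at 0.15. Members of a list can lie in 1 segment, so these counts are not independent.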

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

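The tests of the B6-mMSCs-p28 segments and of the Bc focal calls were chosen after the result was seen; those of the probe residuals were not. The requirement that processed signals and loess values both decide was added to the mixture tests after the slopes of both were known.

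The median p28 minus p12 difference ran in opposite directions in the C57BL/6 and BALB/c arrays on chromosome 3, with medians of -0.26 and 0.49, and on chromosome 4, with -0.35 and 0.28. In the C57BL/6 arrays only distal chromosome 3 (-0.69) and chromosome 4 from 88738012 on (-3.29 over 20 probes, then -0.73) were called lower. The medians thus do not describe the proximal parts. With 1 array each, the difference between the cultures was not tested.

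B6-mMSCs-p28 carried the called segments of TmMSCs while B6-mMSCs-p12 carried none. Independent acquisition at unrelated breakpoints is argued against by 4 shared breakpoints, above the 1 of the rotations. A mixture with at least 20 percent of DNA from unchanged cells stays open: the slope of segment levels on those of TmMSCs was 0.94 (SE 0.03) on processed signals but 0.54 (SE 0.03) on loess values, and the mean over the 20-probe Cdkn2a deletion was -3.23 (SE 0.15) but -2.44 (SE 0.14), against a bound of -2.32. DNA of the TmMSCs line on the array, through a wrong label or cross-contaminated cells, may explain that 99.7% of its called probes were called alike, but a common origin of both cultures predicts the same value, and these explanations cannot be told apart here. Change in the C57BL/6 cells after p12 is argued against by the same 4 breakpoints only if it arose independently of TmMSCs at unrelated breakpoints. With a common origin of both cultures the breakpoints do not decide it.

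Focal calls shared by both Bc arrays may be inherited differences between BALB/c and the spleen reference. For the chromosome 7 region this is argued against by a p28 minus p12 difference of -2.72 (SE 0.21) against its flanks. For the other 6 regions, Rbfox1, Dmd and Luzp1 among them, it stays open: 1 of the 6 regions, that of Mfap1a, differed by over 0.5 (0.55, SE 0.28). Rbfox1 (0.45, SE 0.03) and Dmd (0.31, SE 0.02) stayed under 0.5 but differed by many SE over probes. Luzp1 differed by -0.19 (SE 0.14), and the remaining regions by -0.09 (SE 0.02) and -0.05 (SE 0.04). Loss during culture before p12 is equally untested.

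Probe residuals of B6-mMSCs-p28 ran against those of TmMSCs (r = -0.45 for deviations from the segment means). Intensity-dependent dye bias may account for this, since the correlation was -0.04 after intensity loess, which also lowered the noise SD of B6-mMSCs-p28 to 0.453. GC content of the probes is argued against, since the correlation stayed at -0.45 after GC lowess. No biological explanation was tested.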

How the results depend on the processing

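Most settings were fixed before the data were examined. The GC lowess span and the median signals for normexp were set once the files were read. The tests of overlap and breakpoints on loess values, the breakpoint counts without the shared deletion, the rotations of calls beyond TmMSCs, and the alternatives for gene lists and single chromosomes were chosen after the result was seen. With 1 array per group, sampling error between cultures or tumours is unknown, and SDs over probes do not measure it. No paired analysis was possible because each group has only 1 sample. Of the values compared, 2965 stayed the same, 262 moved and 1 reversed. A count was labelled the same within a fixed fold of the main count, and most gene values within their SD over probes. The SD is wide in B6-mMSCs-p28, so these totals do not measure robustness. The series matrix values moved none of those below, but they are the same log ratios at nearly all spots. Leaving out segments called in every array could change nothing, because B6-mMSCs-p12 had no called segment. Unless stated, the cause was not tested.

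Normexp background correction put Cdkn2a at -1.88 in TmMSCs, -1.61 in T1, -2.08 in RT2, 0.19 in B6-mMSCs-p12, -1.18 in B6-mMSCs-p28, -1.51 in Bc-mMSCs-p12 and -2.01 for Cdkn2a, Bc-mMSCs-p28. Deep loss probes, TmMSCs: 0, T1: 17 and B6-mMSCs-p28: 0. The offset of 50 limits how low the ratios of deep losses can fall. Gained probes, T1: 40558. Higher probes, T1 minus TmMSCs: 17412. Whole chromosomes lost, T1: 1 and Bc-mMSCs-p12: 0, and gained, Bc-mMSCs-p12: 1. The median change per autosomal probe of B6-mMSCs-p28, between values centred in both settings, was -0.216.

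Intensity loess gave deep loss probes, B6-mMSCs-p28: 73. High gain probes, TmMSCs: 31, B6-mMSCs-p28: 10 and Bc-mMSCs-p28: 0. Gained probes, Bc-mMSCs-p28: 53526. Higher probes, T1 minus TmMSCs: 26138. Whole chromosomes gained, Bc-mMSCs-p28: 4, and lost, T1: 1. GC lowess gave whole chromosomes gained, Bc-mMSCs-p12: 1.

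Centring on the mode (the density peak) shifted RT2 by -0.146 and B6-mMSCs-p28 by 0.114. It gave gained probes, T1: 11463 and B6-mMSCs-p28: 51895. Higher probes, T1 minus TmMSCs: 2174, RT2 minus TmMSCs: 7897, RT2 minus T1: 27219, B6-mMSCs-p28 minus B6-mMSCs-p12: 32845 and Bc-mMSCs-p28 minus Bc-mMSCs-p12: 79467. Lower probes, T1 minus TmMSCs: 54744. Whole chromosomes gained, B6-mMSCs-p28: 3 and Bc-mMSCs-p12: 1. Centring on the median of autosome medians gave gained probes, T1: 11463 and Bc-mMSCs-p12: 11669. For Bc-mMSCs-p28 minus Bc-mMSCs-p12 it gave 82479 higher and 31528 lower probes, and whole chromosomes gained, Bc-mMSCs-p12: 1.

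Threshold 0.15 gave gained probes, TmMSCs: 16393, T1: 40570, B6-mMSCs-p28: 38556 and Bc-mMSCs-p12: 46780. Lost probes, Bc-mMSCs-p12: 61931. Higher probes, T1 minus TmMSCs: 26654, RT2 minus T1: 83984, B6-mMSCs-p28 minus B6-mMSCs-p12: 26681 and Bc-mMSCs-p28 minus Bc-mMSCs-p12: 94878. Lower probes, T1 minus TmMSCs: 61146. It gave shared called probes, Bc-mMSCs-p12 and Bc-mMSCs-p28: 40726. Threshold 0.35 gave gained probes, T1: 4878, Bc-mMSCs-p12: 11669 and Bc-mMSCs-p28: 21027. Lost probes, Bc-mMSCs-p12: 6607. Higher probes, T1 minus TmMSCs: 1828, RT2 minus TmMSCs: 7897 and RT2 minus T1: 27219. Lower probes, Bc-mMSCs-p28 minus Bc-mMSCs-p12: 31528. It gave shared called probes, Bc-mMSCs-p12 and Bc-mMSCs-p28: 12055, and shared called probes, T1 and RT2: 37120.

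Penalty 5 gave deep loss probes, T1: 245, and high gain probes, TmMSCs: 32 and Bc-mMSCs-p12: 5. Penalty 20 gave deep loss probes, B6-mMSCs-p28: 0. Deep threshold 0.8 gave deep loss probes, TmMSCs: 7049, and high gain probes, T1: 1867. Deep threshold 1.5 gave high gain probes, T1: 5, RT2: 0 and Bc-mMSCs-p28: 0. Without deep or high probes the median of chromosome 5 in RT2 was -0.06 against 0.45, because the probes removed are those of its strongest gains.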

Other observations

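The tests reported here as values were chosen after the data were seen, except the counts of the gene lists.

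In the families that vary between mouse strains, which include olfactory receptor (Olfr), vomeronasal and Skint genes, 181 of 736 members were lost and 0 gained in TmMSCs, and 181 of 732 lost and 0 gained in B6-mMSCs-p28. Bc-mMSCs-p28 had 248 gained and 188 lost, and B6-mMSCs-p12 had 0 of 726 called. Of all named genes, 14.8% were lost in TmMSCs and in B6-mMSCs-p28, and 4.8% and 4.7% gained. In Bc-mMSCs-p28 35.9% of them were gained and 17.7% lost. Members can lie in the same broad segment, and whether strain plays a part in these counts was not tested. A Bc-mMSCs-p28 gain on chromosome 4 (111611744 to 112104237) held Skint3, Skint4 and Skint9 at 0.55 ± 0.75. The 1 gene that met the lymphocyte receptor prefixes, Ighmbp2, was called gained in RT2 and Bc-mMSCs-p28.

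Macrod2 on chromosome 2 (141486042 to 141536857, 8 probes) was deeply lost in Bc-mMSCs-p28 at -1.35 ± 0.21. A gain of chromosome 9 in Bc-mMSCs-p28 (7508084 to 8368280) held the matrix metalloproteinase genes Mmp7, Mmp8 and Mmp10 beside Birc2 at 0.55 ± 0.20. Of the called probes, 65.4% in p12 were not called the same way in p28, and 81.0% in p28 were not called the same way in p12. Steps inside the shared chromosome 4 deletion left aside, 2 of 16 breakpoints of p12 had no counterpart in p28, and 21 of 35 of p28 had none in p12.

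TmMSCs held small steps on chromosome 5 that ran the same way as those of T1 over part of the chromosome. Before the distal gain, TmMSCs segments stood at 0.11, -0.10, 0.09 (the segment with Kit) and -0.08. T1 segments stood at 0.28, -0.68, 0.34, 0.83 (with Kit), 0.26, -0.69 and 0.24, so the last part of the -0.08 segment of TmMSCs had the opposite sign in T1. Autosomes of TmMSCs with 1 uncalled segment stood from -0.13 (chromosome 13) to 0.15 (chromosome 18), with chromosomes 1, 6 and 10 at 0.11, 0.10 and 0.10. The 0.11 and 0.09 segments of chromosome 5 thus lay at a level common on uncalled chromosomes and show no gain at Kit in TmMSCs. The share of TmMSCs cells with the chromosome 5 changes of T1 was not tested. A loss of 5 probes on chromosome 3 without a named gene was called in TmMSCs (-3.75 ± 2.47), T1 (-3.17 ± 2.21) and RT2 (-3.21 ± 2.53), each with an SD near the size of the mean.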
